A study of Mus musculus with 6 samples.

How the data were processed

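The series holds 6 RNA-seq libraries, 3 of fibro-adipogenic progenitors treated with vehicle and 3 of progenitors treated with C1q at 100 µg/ml, each made from 10 ng of total RNA with a low-input SMART-Seq cDNA kit. Groups and replicate numbers came from the sample titles and the treatment labels. The labels do not say whether replicates came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical. No pair of replicates agreed within sampling noise, as the chi-square per degree of freedom was 21.1 to 46.6.

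The deposited table is a normalised signal, read counts per Entrez gene divided by a size factor per library, although the file headers call the columns featureCounts counts. Trimmomatic, HISAT2, featureCounts and DESeq2 with build mm10 are named in the submitters' processing notes. Versions, annotation and strand setting are not given in the sources used here. Within each library the values are whole multiples of what 1 read is worth, and 100% of them came out as whole reads within 0.001 of a read, so the reads were recovered exactly. The library totals are from 5379209 reads in control 3 to 38861152 in control 1. These are reads on genes of the table, not all reads sequenced. One read is worth 4.25 units of the normalised count in control 3 and 0.583 to 0.975 in the other libraries, so low values of control 3 are the least precise. The lowest mean of any gene is 1.00, so genes below a mean of about 1 appear to have been left out before deposit. The planned test had assumed raw counts. Because the deposited values are normalised, the test laid down for that case was used as the main one, and count tests on the recovered reads served as alternatives.

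Gene symbols and coordinates came from a RefSeq gene table of assembly GRCm38.p6 matched on Entrez gene ID: 16077 of 16671 IDs had a symbol and 594 did not. The length of the longest annotated transcript and the median GC content over a gene's transcripts came from GENCODE vM21 of the same assembly. They were available for 14933 IDs (89.6%). Without a stated strand setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart, and genes with near-identical copies elsewhere, such as Prl2c2, C4b, ribosomal protein genes and mitochondrial genes with nuclear copies, are uncertain. Mitochondrial genes were taken as the 15 genes on chromosome MT, since the table's symbols for them lack the prefix that had been planned for finding them. No haemoglobin gene is in the table.

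The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1) over genes with a mean of at least 1, which removed 0 genes, with Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Group values are means ± SD of the normalised read count over 3 libraries. The 29 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera against all other genes with a preset correlation of 0.01, again with the correlation estimated per list, and with fry, and each list's members were also adjusted over the list alone. The rule named the 10 largest rises and the 10 largest falls among called genes with a mean log2(value + 1) of at least 5, a symbol that is not a provisional name and groups that do not overlap. It added up to 4 members with the lowest p in each list, and Axin2, Col1a1, Col3a1, Acta2, Pdgfra, Ly6a, C1qa, C1qb and C1qc in any case. This gave 137 genes, of which those that describe each list are named, and Myh7 was named in addition after its value was seen. Library-level measures (10) were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

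Whether the shared replicate numbers pair the libraries was checked by the correlation of their deviations from the group means over all genes. It was 0.123, 0.175 and 0.132 for the same-numbered pairs 1, 2 and 3, all above the limit of 0.1 set for pairing. The numbers were therefore taken to pair the libraries, from the data and not from a statement in the labels. With 3 libraries per group few other matchings are possible, so chance could give this result and the pairing stays uncertain. The main test did not use it, and the replicate block served as an alternative. Alternatives planned beforehand were other pseudocounts and thresholds, edgeR 4.0.16 with other scalings, filters and fits, DESeq2 1.42.0 and limma-voom on the recovered reads, the replicate number as a block, leaving out each library, and an estimated correlation for the lists. Alternatives chosen after seeing the data were edgeR with TMM scaling (the test planned for raw counts), array weights, thinning every library to 5379209 reads, and removal of a loess trend (span 0.5, fitted on genes with a mean of at least 20) on transcript length, alone and with the block, or on GC content with the block.

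The tests were tried on simulated data with 200 changed genes in each of 3 runs of the C1q against control design over 16528 genes. The limma-trend test recovered 38.8% of 1.5-fold, 73.1% of 2-fold and 97.5% of 4-fold changes with 0 wrong signs, and 7.52% of its calls were false. That false share is above the adjusted p threshold of 0.05. The simulated genes were drawn independently and without a trend on transcript length. Far fewer genes changed than the 6389 called in the data, so these rates need not hold there. The camera test called 20 of 20 shifted lists of 25 genes (1.5-fold) and 1 of 560 unchanged lists, drawn without correlation between genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the library measures, and matplotlib 3.10.9 for the plots.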

Results

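Gene expression was measured by low-input RNA sequencing, with cDNA made from 10 ng of total RNA per library, in fibro-adipogenic progenitors (FAPs), the mesenchymal stromal cells that lie between muscle fibres, sorted by flow cytometry from the hindlimb muscles of wild-type mice 4 to 5 months old. The cells had received either vehicle or C1q at 100 µg/ml. C1q is the recognition protein that starts the classical complement pathway and is assembled from the products of C1qa, C1qb and C1qc. Each group held 3 libraries. The table gave normalised read counts for 16671 genes, and the reads behind them numbered 38861152, 29325341 and 5379209 in control replicates 1, 2 and 3 and 31929119, 24046020 and 29818424 in C1q replicates 1, 2 and 3. Control replicate 3 was therefore the shallowest library, with 15255 genes detected against 16413 to 16549 in the others. The labels name the cells as FAPs, while their RNA extraction text speaks of muscle stem cells. The comparison asks how exposure to C1q changes gene expression in these cells.

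FAPs treated with C1q differed from vehicle-treated cells at 6389 of 16671 genes, of which 3277 were higher and 3112 were lower with C1q (limma-trend, Benjamini-Hochberg adjusted p below 0.05). The change reached at least 2-fold on the log2(value + 1) scale for 865 higher and 516 lower genes. Collagens (12 of 18) and FAP identity markers (16 of 27) were mostly higher with C1q, but only 7 and 13 were with a trend on transcript length removed. Of 24 complement genes 9 were higher and 0 lower, and of 21 targets of Wnt signalling 9 were higher and 1 lower. Genes of cholesterol synthesis, glycolysis, oxidative phosphorylation, the unfolded protein response, antioxidant defence and the immediate early response were mostly lower. The groups did not overlap at 8690 genes (52.1%). Chance gives 10% for a single gene, but genes are correlated, and the share was not computed for other splits of the libraries. Other tests on the reads recovered from the table called similar numbers, 6946 genes with edgeR and 6492 with DESeq2.

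The largest rise was in Kera, which encodes the small leucine-rich proteoglycan keratocan (Entrez gene 16545, chromosome 10, 97606962 to 97613688, coordinates in GRCm38 throughout) and went from a normalised read count of 39.7 ± 44.4 in controls to 668 ± 732 with C1q (SD, n = 3 throughout), a 20.2-fold rise with an adjusted p of 0.0189. C1q replicate 3 alone stood at 1514, and without it the log2 fold change was 3.46 in place of 4.34, with an adjusted p of 0.0619. It was 3.18 without control replicate 1 and 5.35 without control replicate 3. Matn4, which encodes a matrilin, rose 13.8-fold from 21.7 ± 14.4 to 279 ± 42.3. Scg2, which encodes the secretory granule protein secretogranin II (Entrez gene 20254, chromosome 1, 79434366 to 79440026), rose 13.1-fold from 245 ± 54.8 to 3362 ± 1344. Penk, the precursor of the enkephalin opioid peptides (Entrez gene 18619, chromosome 4, 4133536 to 4138815), rose 11.2-fold from 534 ± 138 to 5912 ± 811, with a log2 fold change of 3.49 ± 0.18 (SE) and an adjusted p of 1.12e-04. Pappa2, a protease that cleaves insulin-like growth factor binding proteins, rose 10.6-fold from 111 ± 33.6 to 1170 ± 205. The other genes among the 10 largest rises were Cpxm2 (12.7-fold), Col6a5, a collagen VI chain (11.4-fold), the calcium-dependent kinase gene Camk4 (10.3-fold), Prss35 (9.75-fold) and Syt13 (9.67-fold), with adjusted p between 0.00177 and 0.00589. Some of the largest rises rest on few control reads. Control replicates 1, 2 and 3 held 22, 20 and 1 reads of Camk4 and 26, 28 and 1 of Syt13. They held 9, 62 and 8 reads of Col6a5, 21, 19 and 9 of Matn4, and 6, 34 and 21 of Kera. Leaving out 1 library moved the fold by over 1.5 times for Cpxm2 (log2 fold change 3.67, and 2.92 without control replicate 1 or 4.33 without control replicate 3), Col6a5 (3.51, and 2.60 without control replicate 1) and Syt13 (3.27, and 2.65 without control replicate 3).

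The largest fall was in Cck, the precursor of the peptide hormone cholecystokinin (Entrez gene 12424, chromosome 9, 121489824 to 121495694), which went from 1076 ± 381 to 41.9 ± 17.6, 25.2-fold lower with an adjusted p of 2.06e-04. The metallothionein genes Mt2 and Mt1, whose products bind metal ions, lie beside each other on chromosome 8 (94172618 to 94173567 and 94178883 to 94180327). Mt2 was 9.82-fold lower (5436 ± 656 against 556 ± 98.9) and Mt1 8.17-fold lower (6604 ± 425 against 810 ± 91.6), with adjusted p of 7.90e-05 and 4.20e-05. Spp1, which encodes osteopontin (Entrez gene 20750, chromosome 5, 104435111 to 104441053), fell 6.93-fold from 40069 ± 13203 to 5709 ± 1727. The circulating stress factors Gdf15 and Fgf21 were 5.55-fold and 7.63-fold lower. Control replicate 1 held most of the Fgf21 signal (743 against 130 and 80.8), and the adjusted p of 0.0167 became 0.0551 without C1q replicate 2 and 0.0557 without C1q replicate 3. Atp6v0d2, a subunit of the vacuolar proton pump, was 10.6-fold lower, and the steroid-metabolising reductase gene Akr1c18 was 13.8-fold lower. Prl2c2 was 16.9-fold lower, but it has near-identical copies in the genome, so its reads are uncertain. The muscle creatine kinase gene Ckm was 5.97-fold lower (adjusted p 0.0139, and 0.0527 without C1q replicate 1). Ckm varied between controls together with other muscle-lineage genes, falling from control replicate 1 to 3. Prl2c2, Akr1c18 (394, 216 and 123), Fgf21 and Gdf15 (161, 113 and 80.8) fell in the same order. Cck, Atp6v0d2, Mt1, Mt2 and Spp1 did not. Over the controls Kera, Matn4, Cpxm2 and Prss35 ran the opposite way, and the rest of the largest rises followed neither order. Whether these orders share a cause with that of the muscle-lineage genes was not tested. Leaving out 1 library moved the fold by over 1.5 times for Prl2c2 (log2 fold change -4.08, and -3.36 and -4.80 without control replicates 1 and 3 and -4.81 and -3.24 without C1q replicates 1 and 3), Akr1c18 (-3.79, and -4.41 and -3.02 without C1q replicates 1 and 3), Fgf21 (-2.93, and -1.98 and -3.58 without control replicates 1 and 3) and Ckm (-2.58, and -1.93 and -3.28 without control replicates 1 and 3). Annotated exons on the opposite strand overlap Matn4, Cpxm2, Penk, Camk4, Mt2 and Ckm, and the strand setting of the counting is not stated, so reads of these overlapping genes cannot be separated.

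**Figure D1:**
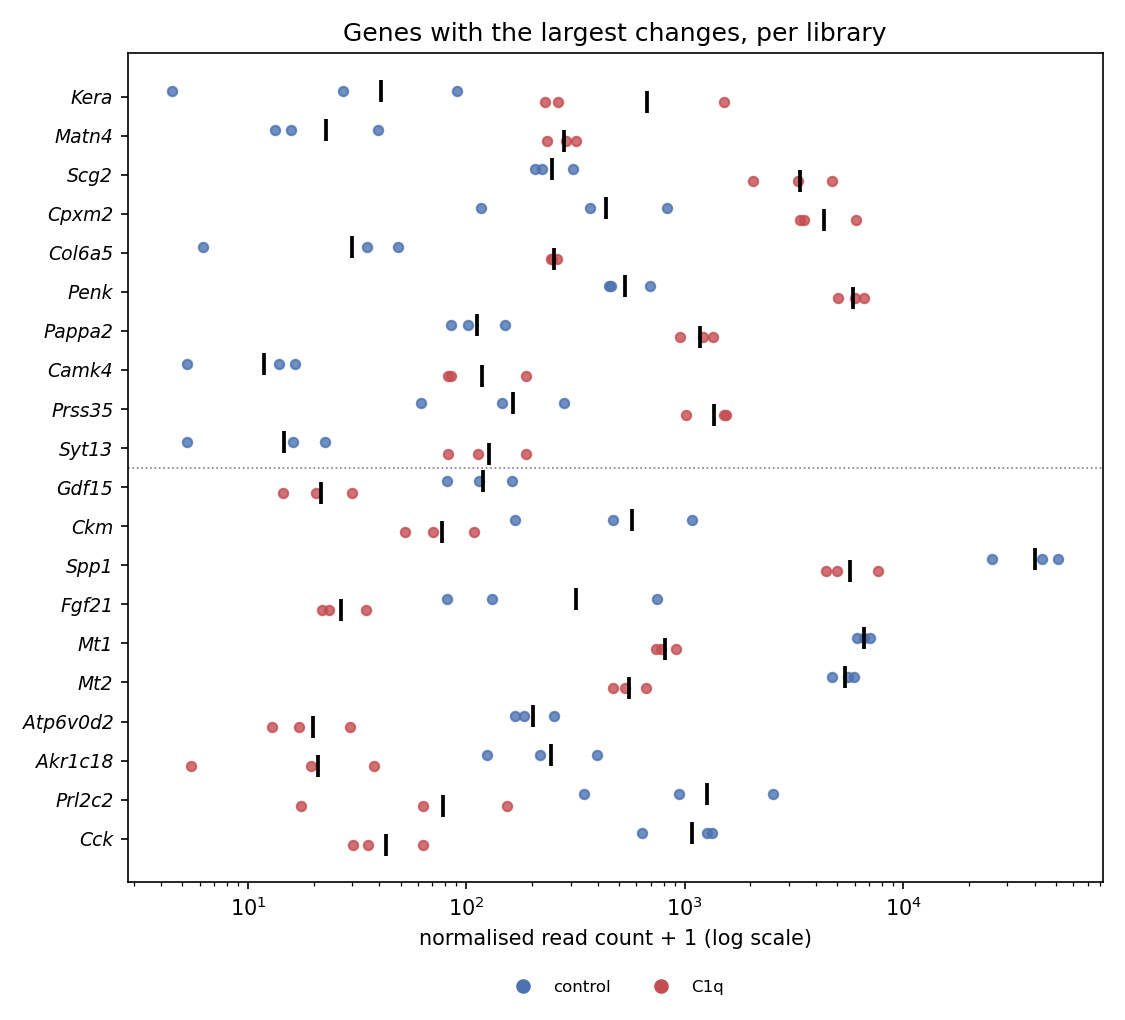
Normalised read count plus 1 on a log axis for the 10 genes with the largest rises (above the dotted line) and the 10 with the largest falls (below it) with C1q. Each point is 1 library, black bars are group means of 3 libraries, and in each of the 20 genes the control and C1q libraries do not overlap, as for Penk at 534 ± 138 against 5912 ± 811.

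Of 18 collagen genes measured, 12 were higher and 1 was lower (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.91. Once a trend of fold change on transcript length was removed, 7 were higher and 1 lower with a median of 0.52. The adjusted p was 2.48e-04 with camera at its preset correlation, and the adjusted p = 0.416 with an estimated correlation. Col12a1, a fibril-associated collagen, went from 3819 ± 1395 to 20523 ± 4339 (log2 fold change 2.47, adjusted p 5.25e-04), Col8a1 from 3931 ± 797 to 12944 ± 835 (1.74, adjusted p 2.75e-04) and Col11a1 from 1348 ± 303 to 3739 ± 412 (1.49, adjusted p 4.99e-04). The fibrillar collagen gene Col1a1 rose from 156830 ± 11398 to 271034 ± 52892 (0.77, adjusted p 0.0287), a call lost without control replicate 1 (0.0692), control replicate 2 (0.0539), C1q replicate 1 (0.0765) or C1q replicate 2 (0.0889). Col3a1 stood at 222822 ± 47890 and 353413 ± 46914 and was not called (0.68, adjusted p 0.0803, and 0.0340 with edgeR). Among 27 matrix glycoproteins, proteoglycans and collagen-processing genes, 8 were higher and 2 lower, both over all genes and adjusted over the list alone (median 0.32, camera adjusted p 0.0455, and adjusted p = 0.592 with an estimated correlation). Eln, which encodes elastin, rose from 3865 ± 643 to 15100 ± 1828, Thbs1, which encodes thrombospondin 1, from 28846 ± 7331 to 129197 ± 18965, the proteoglycan gene Lum from 1552 ± 832 to 7490 ± 1963, and Postn, which encodes periostin, from 66894 ± 19483 to 170637 ± 26694 (adjusted p 1.96e-04 to 0.00363). Fmod rose too, and it also counts among the tenocyte markers below. This list lost its camera call without control replicate 1 (0.0685) or 2 (0.0976) or C1q replicate 1 (0.0587) or 2 (0.0666).

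Markers of FAP and fibroblast identity were higher with C1q at 16 of 27 genes and lower at 1, with the same counts adjusted over the list alone (median log2 fold change 0.62, camera adjusted p 1.32e-04, and adjusted p = 0.288 with an estimated correlation). Pi16, a marker of fibroblasts shared by many tissues, rose from 244 ± 84.2 to 1630 ± 499 (log2 fold change 2.74, adjusted p 5.34e-04), and the matrix protein gene Dpt from 5031 ± 645 to 10651 ± 1337. The FAP surface receptor gene Pdgfra rose from 19529 ± 4229 to 32857 ± 1308 (0.77, adjusted p 0.00641). The surface marker gene Ly6a (Sca-1) stood at 14045 ± 596 and 15680 ± 2136 and was not called (0.15, adjusted p 0.336), but was at 0.67 (adjusted p 0.00361) once a trend on transcript length was removed. Among 26 trophic factor genes of FAPs, 10 were higher and 1 was lower (12 and 2 adjusted over the list alone), with a median of 0.54, a camera adjusted p of 0.0406, and adjusted p = 0.288 with an estimated correlation. They included Fst, the activin and myostatin antagonist follistatin (1198 ± 430 to 3571 ± 145), the growth factor genes Hgf (1033 ± 271 to 2152 ± 201) and Fgf2 (92.1 ± 32.5 to 315 ± 31.4), and Bmp3 (34.3 ± 7.76 to 192 ± 40.0). Without control replicate 2 or C1q replicate 1 the camera adjusted p of this list was 0.0556 and 0.0587.

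C1q has been reported to activate Wnt signalling in muscle, and 21 targets of Wnt and beta-catenin were measured. Of these, 9 were higher and 1 was lower, over all genes and adjusted over the list alone (median 0.41, or 0.24 with a trend on transcript length removed, camera adjusted p 0.00741, and adjusted p = 0.229 with an estimated correlation). The feedback inhibitor genes Nkd1 and Nkd2 rose from 123 ± 29.4 to 358 ± 24.1 and from 117 ± 6.13 to 238 ± 31.4, the receptor gene Lgr5 from 251 ± 95.2 to 974 ± 129, and Ccdc80 from 10449 ± 738 to 29697 ± 1662 (adjusted p 1.48e-04 to 0.00118). Ccdc80 was placed in this list beforehand, and whether Wnt signalling raises it in these cells was not tested. Axin2, a widely used readout of the pathway, stood at 103 ± 7.77 and 137 ± 21.8 and was not called (log2 fold change 0.41 ± 0.16 SE, adjusted p 0.0868, and 0.117 with the replicate number as a block). Among 17 reported receptors and binding partners of C1q, 7 were higher and 3 lower, over all genes and adjusted over the list alone (camera adjusted p 0.0658). The Wnt receptor gene Fzd4 rose from 714 ± 79.1 to 2038 ± 326, and C1qbp changed by -1.05. The co-receptor gene Lrp5 was called higher at 0.62, but only at 0.09, with an adjusted p of 0.309, once a trend of fold change on transcript length was removed.

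Of 24 measured complement components and regulators, 9 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.75, a camera adjusted p of 0.00347, and adjusted p = 0.416 with an estimated correlation. C3, the central component, rose from 5144 ± 1892 to 26225 ± 4732 (log2 fold change 2.40, adjusted p 5.85e-04), and Cfb, of the alternative pathway, from 2781 ± 648 to 5494 ± 360.5. C4b (0.65) shares sequence with C4a, so its reads are uncertain. The mRNAs of the C1q chains were near the detection limit: C1qa had 8 and 14 reads in replicate 2 of the control and C1q groups and 0 in the other 4 libraries, and neither C1qb nor C1qc was called (adjusted p 0.487 and 0.705). Among 37 interferon-stimulated genes, 8 were higher and 1 was lower (8 and 0 adjusted over the list alone), with a median of 0.47, a camera adjusted p of 0.0234, and adjusted p = 0.638 with an estimated correlation. The count of higher genes is close to the share over all genes, where 3277 of 16671 were higher. Gbp2 and Gbp5, which encode guanylate-binding proteins, rose from 427 ± 126 to 954 ± 74.5 and from 26.9 ± 9.78 to 106 ± 31.5. This list was not called without control replicate 1 (median 0.18, adjusted p 0.161) or C1q replicate 2 (0.30, adjusted p 0.0788), nor with edgeR (0.0646).

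All but 2 of 24 cholesterol synthesis genes were called, 22 lower and 0 higher, over all genes and adjusted over the list alone (median -0.93, camera adjusted p 8.34e-11, and adjusted p = 0.416 with an estimated correlation). Fdps, which makes farnesyl diphosphate, went from 4946 ± 688 to 1719 ± 149 (log2 fold change -1.52, adjusted p 2.07e-04) and Acat2 from 2668 ± 360 to 967 ± 95.2 (-1.46, adjusted p 2.38e-04). Mvk and Fdft1 changed by -1.03 and -1.14, and annotated exons of Ctsb overlap Fdft1 on the opposite strand. Such overlaps also affect other genes named in these results, so their reads are uncertain in the same way. Among them are Junb (with Prdx2), Fgf2 (Nudt6), Shmt2 (Ndufa4l2), Timp3 (Syn3), Tk1 (Afmid), Cebpb (Tmem189) and Manf (Dcaf1). Among 27 genes of hypoxia and glycolysis, 17 were lower and 1 was higher (18 and 1 adjusted over the list alone), with a median of -0.54, a camera adjusted p of 1.47e-07, and adjusted p = 0.220 with an estimated correlation. Ldha, which encodes lactate dehydrogenase A, went from 19367 ± 640 to 9502 ± 482, the glycolytic kinase gene Pgk1 from 8326 ± 365 to 4229 ± 10.7, and the lactate transporter gene Slc16a3 from 2356 ± 201 to 1011 ± 50.8. Mif, which encodes a cytokine, fell from 8045 ± 459 to 2148 ± 122 (-1.91, adjusted p 7.90e-05). Nuclear genes of oxidative phosphorylation were lower at 31 of 33 and higher at 0, over all genes and adjusted over the list alone (median -0.73, camera adjusted p 3.08e-14, and adjusted p = 0.399 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, went from 1733 ± 166 to 859 ± 40.5. Many genes of this list have short transcripts, and the median was -0.35 once the length trend was removed. Ndufa1 and Ndufa2 then changed by only -0.08 and -0.11, with adjusted p of 0.448 and 0.147. The share of the normalised reads on mitochondrially encoded genes was 5.29%, 4.76% and 3.98% in control replicates 1 to 3 and 1.85%, 2.25% and 2.01% in C1q replicates 1 to 3, a difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow (0.5 adjusted over 10 library measures).

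Of 28 genes of the unfolded protein and integrated stress responses, 19 were lower and 1 was higher (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.53, a camera adjusted p of 3.37e-06, and adjusted p = 0.344 with an estimated correlation. They included the serine and folate pathway enzyme genes Psat1 (4004 ± 608 to 1870 ± 196) and Shmt2 (2181 ± 217 to 1211 ± 86.4), the glutathione-degrading enzyme gene Chac1 (212 ± 34.8 to 79.1 ± 10.6) and Manf (2785 ± 83.3 to 1726 ± 43.1). Immediate early and heat shock genes were lower at 18 of 30 and higher at 1 (20 and 1 adjusted over the list alone), with a median of -0.65, a camera adjusted p of 9.23e-06, and adjusted p = 0.164 with an estimated correlation. The transcription factor genes Fos and Junb fell from 428 ± 79.4 to 143 ± 11.4 and from 2749 ± 250.6 to 1647 ± 38.2. Targets of the antioxidant regulator NRF2 were lower at 13 of 21 and higher at 1 (14 and 1 adjusted over the list alone), with a median of -0.51, a camera adjusted p of 9.23e-06, and adjusted p = 0.229 with an estimated correlation. Besides Mt1 and Mt2, the haem oxygenase gene Hmox1 fell from 4764 ± 852 to 1822 ± 60.9 and the peroxiredoxin gene Prdx1 from 11700 ± 916 to 6533 ± 297. Among 21 p53 target and senescence genes, 6 were lower and 2 higher, over all genes and adjusted over the list alone (median -0.36, camera adjusted p 0.0448, and adjusted p = 0.638 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a stood at 8683 ± 4265 and 3070 ± 480 (-1.40, adjusted p 0.0113) and the pro-apoptotic gene Bax at 2187 ± 242 and 928 ± 132 (-1.24, adjusted p 3.83e-04). This list lost its call without control replicate 1 (median -0.14, adjusted p 0.127), control replicate 2 (-0.39, adjusted p 0.0556) or C1q replicate 3 (-0.23, adjusted p 0.169), and with edgeR (-0.48, adjusted p 0.0646). Of 40 cell cycle genes, 14 were lower and 1 was higher, over all genes and adjusted over the list alone (median -0.27, camera adjusted p 0.00741, 0.0556 without control replicate 2, and adjusted p = 0.612 with an estimated correlation). The thymidine kinase gene Tk1 and the replication clamp gene Pcna changed by -0.85 and -0.57.

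Another 6 lists were not called by camera. Of 18 myofibroblast contractile genes, 5 were higher and 4 lower (6 and 4 adjusted over the list alone, camera adjusted p 0.704). Acta2, the smooth muscle actin of myofibroblasts, fell from 14924 ± 1193 to 10164 ± 776 (log2 fold change -0.55, adjusted p 0.00320), whereas Palld, Cdh11 and Itga11 changed by 1.00, 0.99 and 1.15. Of 22 targets of TGF-beta, 9 were higher and 3 lower (11 and 4 adjusted over the list alone, camera adjusted p 0.119), among them Ltbp2 at 1.60 and the protease inhibitor gene Timp1 at -1.11. Of 25 adipogenic genes, 0 were higher and 2 lower (0 and 1 adjusted over the list alone, camera adjusted p 0.954). The camera test put this list below the other genes, although its median was 0.19 and its mean 0.22. That median was -0.05 without control replicate 3 and 0.40 without C1q replicate 1. Its called members were Cebpb, an early adipogenic transcription factor (4492 ± 307 to 2358 ± 148), and the lipoprotein lipase gene Lpl (-0.50, adjusted p 0.0453). The call of Lpl was lost without control replicate 2 (0.105) or 3 (0.0654) or any single C1q replicate (0.153, 0.0540 and 0.0963 without 1, 2 and 3). Of 25 genes of NF-kB and cytokines, 5 were higher and 7 lower (5 and 9 adjusted over the list alone, camera adjusted p 0.496), with a median of 0.05, a mean of -0.35 and a test direction toward lower. The median was -0.12 and -0.06 without control replicates 2 and 3, and 0.03 without C1q replicate 2. The chemokine gene Ccl2 was at 2947 ± 1734 and 481 ± 70.9 (-2.45, adjusted p 0.00199), the interleukin 33 receptor gene Il1rl1 at 4359 ± 324 and 1101 ± 77.2 (-1.98), and Birc3 and Nfkb1 changed by 0.60 and 0.36. Of 25 matrix-degrading proteases and inhibitors, 4 were higher and 11 lower (5 and 13 adjusted over the list alone), with a camera adjusted p of 0.0621 that became 0.0427 with the replicate number as a block and 0.0269 without C1q replicate 2, and adjusted p = 0.416 with an estimated correlation. The cathepsin gene Ctsk changed by -1.13 and the inhibitor gene Timp3 by 1.74. Of 20 osteogenic and chondrogenic genes, 5 were higher and 2 lower, over all genes and adjusted over the list alone (camera adjusted p 0.405). The cartilage matrix genes Cilp (21064 ± 8391 to 83615 ± 1905) and Comp (8898 ± 4282 to 29061 ± 6937) rose, while Spp1 fell.

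**Figure D2:**
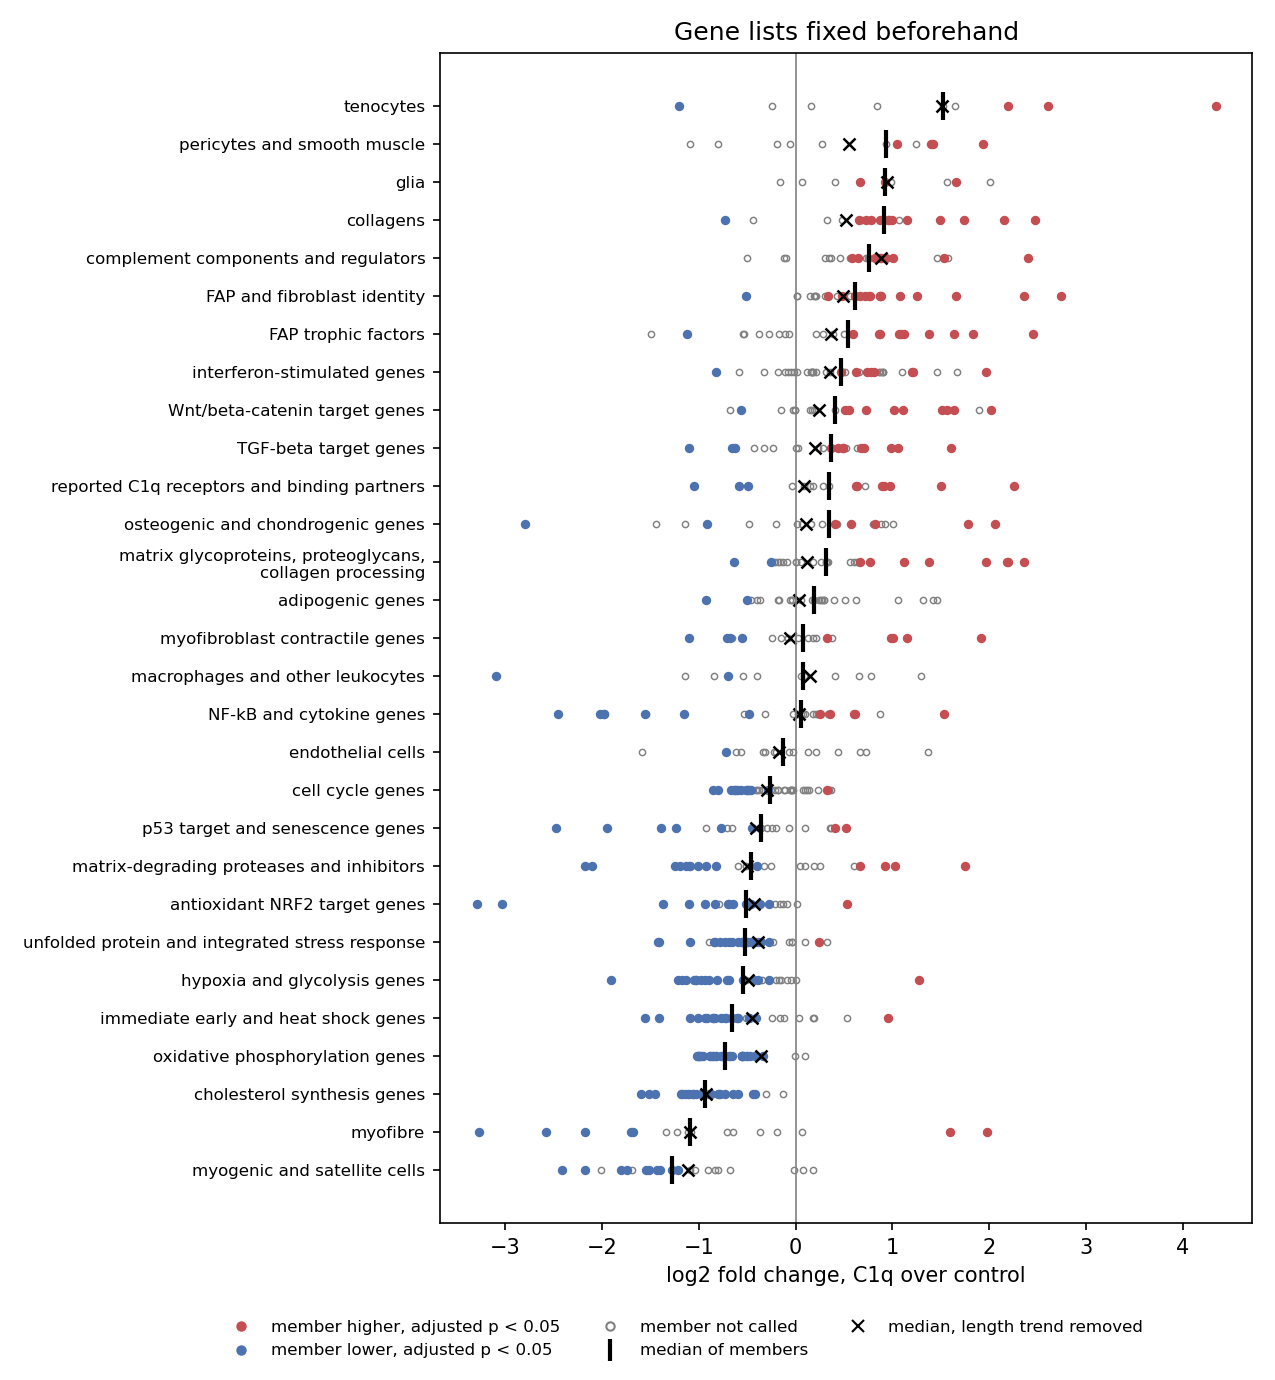
Log2 fold change, C1q over control, of every measured member of the 29 gene lists chosen before the data were examined, in order of the list median. Filled points passed an adjusted p of 0.05 in limma-trend, black bars are medians over members and crosses are medians with the transcript length trend removed, which moved the oxidative phosphorylation genes from -0.73 to -0.35 and left the cholesterol synthesis genes at -0.93.

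Markers of other cell types of muscle were examined in the same way. Of 21 myogenic and satellite cell genes, 10 were lower and 0 higher, over all genes and adjusted over the list alone (median -1.28, camera adjusted p 4.02e-04, and adjusted p = 0.552 with an estimated correlation). The myosin light chain gene Mylpf stood at 10217 ± 6778 and 1952 ± 438 and the cardiac actin gene Actc1 at 11269 ± 6256 and 2928 ± 732 (adjusted p 0.00811 and 0.0103). Of 16 myofibre genes, 5 were lower and 2 higher (7 and 2 adjusted over the list alone, camera adjusted p 0.0455, and adjusted p = 0.638 with an estimated correlation). The higher pair was Myh2, a fast myosin heavy chain at 73.5 ± 29.2 and 306 ± 161, and Myh7, the slow myosin heavy chain, which was picked out after its values were seen. The median of this list was -1.10, and it lost its call without control replicate 1 (median -0.61, adjusted p 0.0775), control replicate 2 (0.146), C1q replicate 1 (0.106) or C1q replicate 3 (0.0526), and with edgeR (0.0959). The 37 muscle-lineage genes of both lists made up 0.901%, 0.490% and 0.258% of the normalised reads in control replicates 1, 2 and 3 and 0.161%, 0.234% and 0.217% in C1q replicates 1, 2 and 3. The share was lower with C1q in each same-numbered pair, and the controls differed from each other more than control replicate 3 differed from the C1q libraries. These genes moved in the same direction as the metabolic and stress-response lists.

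**Figure D3:**
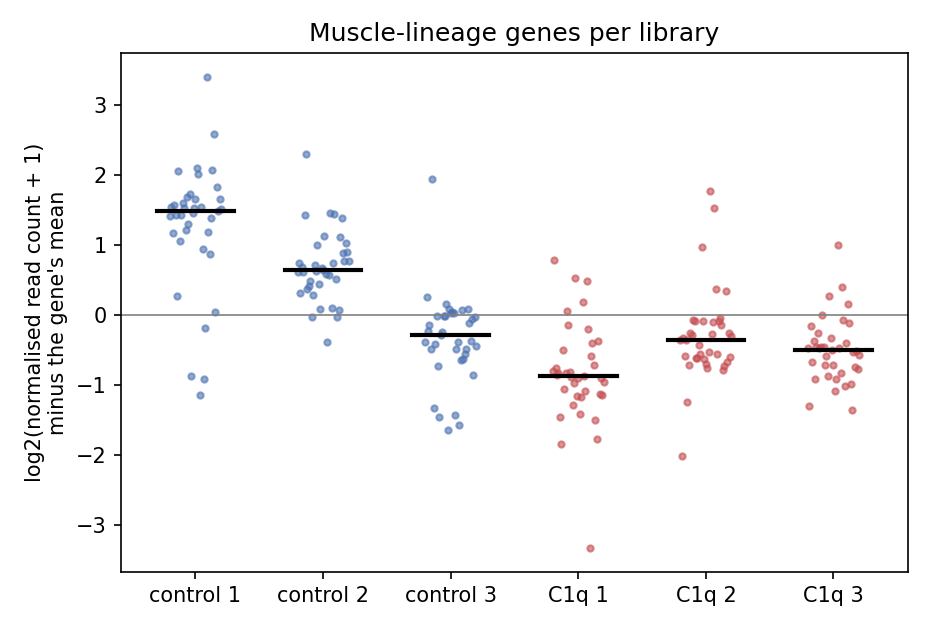
Log2(normalised read count + 1) minus the mean of the 6 libraries for 37 muscle-lineage genes, 1 point per gene and library. Black bars are medians over genes, which stood at 1.49, 0.64 and -0.29 in control replicates 1, 2 and 3 and at -0.88, -0.35 and -0.50 in C1q replicates 1, 2 and 3.

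Tenocyte markers were higher at 3 of 9 genes and lower at 1 (4 and 1 adjusted over the list alone, median log2 fold change 1.52, camera adjusted p 0.213), with Tnmd, which encodes tenomodulin, at 324 ± 164 and 1851 ± 504 and the tendon transcription factor gene Scx at 358 ± 55.4 and 156 ± 37.9. The other called members were Kera, the largest rise, and Fmod, also in the matrix glycoprotein list (5067 ± 2702 to 21079 ± 5898). Over the other settings the tenocyte median ran from 0.81 to 1.70. Camera called this list with the block and the length trend (adjusted p 0.0415) or the GC trend (0.0341) removed. Pericyte and smooth muscle markers were higher at 4 of 11 and lower at 0, over all genes and adjusted over the list alone (median 0.93, or 0.54 without control replicate 1, 0.46 without control replicate 3 and 0.55 with the length trend removed, camera adjusted p 0.125), including Steap4 (1.40) and Notch3 (1.05). Glial markers were higher at 3 of 9 and lower at 0, over all genes and adjusted over the list alone (median 0.92, camera adjusted p 0.146). Leukocyte markers were lower at 2 of 14 and higher at 0 (1 and 0 adjusted over the list alone, camera adjusted p 0.405). Their median was 0.07 while their mean of -0.23 and the test pointed lower. This median turned with single libraries, to -0.15, -0.46 and -0.71 without control replicate 1, control replicate 3 and C1q replicate 2. It was 0.18 without control replicate 2. Cx3cr1 had 20, 16 and 5 reads in the controls and 2, 0 and 2 with C1q, and its call was lost when the libraries were thinned to equal depth (adjusted p 0.346). Endothelial markers were lower at 1 of 16 and higher at 0 (0 and 0 adjusted over the list alone, camera adjusted p 0.847).

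Fold changes also followed transcript length. Across 12454 genes the Spearman correlation of log2 fold change with the length of the longest annotated transcript was 0.47, where genes are not independent replicates. The median log2 fold change went from -0.67 for transcripts under 1000 nucleotides to 0.59 for those over 10000. With this trend removed, 4991 of 14933 genes with a length were called, 2183 higher and 2808 lower. Of the 3913 calls shared with the first test, 3874 had the same direction. The collagen, Wnt target, interferon, complement, FAP identity and trophic factor lists kept their camera calls, and so did the lists called lower other than the p53 list (adjusted p 0.0791, median -0.36 before and -0.41 after) and the myofibre list (0.0587, -1.10 before and -1.09 after). With the replicate block as well, camera called the p53 list (adjusted p 0.00925) but not the myofibre list (0.0619). The medians of the collagen and Wnt target lists went from 0.91 to 0.52 and from 0.41 to 0.24, with 7 genes higher in each in place of 12 and 9, and 5 interferon-stimulated genes were higher in place of 8. The matrix glycoprotein list lost its call (0.187, median 0.32 before and 0.12 after), and the rises of Pdgfra and Col1a1 then missed the threshold (0.37 and 0.45, adjusted p 0.0945 and 0.188). The log2 fold changes of Mif, Bax, Timp1 and Pcna became -1.16, -0.79, -0.55 and -0.28, and those of Palld, Notch3, C4b and Nfkb1 became 0.64, 0.57, 0.37 and 0.22, all still called. Cck went from -4.65 to -4.05, Mt2 from -3.30 to -2.47 and Col12a1 from 2.47 to 1.85, also still called.

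**Figure D4:**
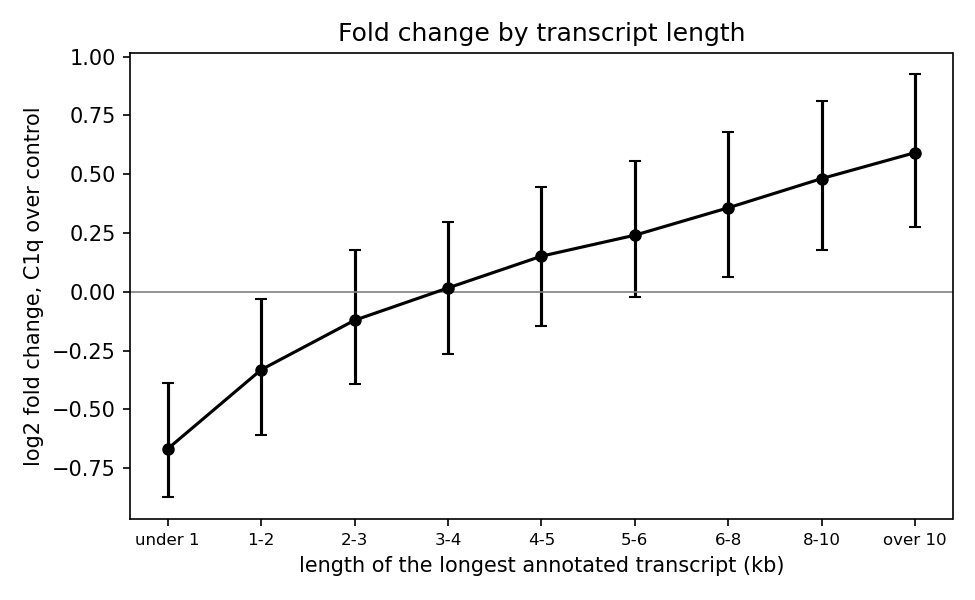
Median log2 fold change, C1q over control, of 12454 genes with a mean normalised read count of at least 20, in bins of transcript length in kilobases. Bars span the lower to the upper quartile of the genes in a bin, and the medians go from -0.67 in the shortest bin to 0.59 in the longest.

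Of the 29 lists, 17 were called by camera with a preset correlation of 0.01 between genes and 0 when the correlation was estimated from the data, where 4 had an unadjusted p below 0.05. The rotation test fry called 14 lists as moving in 1 direction and 26 as changed in either direction. Camera with the preset correlation and fry in 1 direction both called 11 lists. Fry did not call the interferon (adjusted p 0.201), p53 (0.167), cell cycle (0.0934), myogenic (0.0934), matrix glycoprotein (0.0576) or myofibre (0.266) lists. It called the C1q receptor (1.60e-04), protease (0.00755) and pericyte (0.0379) lists, which camera did not. Splits of the 6 libraries that mix the groups also gave 9 to 17 lists by camera, and 0 genes by limma-trend.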

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

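Tests chosen after the data were seen are edgeR with TMM scaling, array weights, thinning to equal depth and the removal of length or GC trends, and the others were planned. Across 23 other settings at the same threshold (adjusted p below 0.05) and the same tests of lists, the count of changed genes ran from 4607 to 7413 against 6389, and every shared call had the same direction, except that 3874 of 3913 did with the length trend removed and 4017 of 4055 with that removal and the block. A stricter threshold of 0.01 left 3860 genes, 1943 higher and 1917 lower, and 910 changed at least 2-fold, as a lower threshold must. With the length trend removed the higher genes numbered 2183, and higher genes made up 43.7% of calls against 51.3%. That setting tested 14933 genes in place of 16671, and the cause was not tested. The median log2 fold change of all genes stayed between -0.01 and 0.04 in every setting. With an estimated correlation 0 lists were called in place of 17. The estimate was below 0.01 for the Wnt target (-0.0359), trophic factor (-0.000693) and immediate early (-0.0138) lists. Their unadjusted camera p still rose, from 0.00307 to 0.0316, 0.0196 to 0.0595 and 1.91e-06 to 0.00565. This argues against a larger correlation as the cause for these lists. The other called lists had estimates from 0.0552 (hypoxia and glycolysis) to 0.816 (cholesterol synthesis). The cause was not tested further. The setting with no filter on low values tested the same genes and says nothing.

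Leaving out each library in turn gave 4607 to 7242 changed genes (2332 to 3659 higher, 2264 to 3583 lower), 1076 to 1771 changed at least 2-fold and 12 to 17 lists. Without the shallow control replicate 3 the count was 7242, and without control replicate 1, which had the most muscle-lineage reads, it was 5402. With the replicate block 6833 genes were called (3548 higher, 3285 lower), 1467 of them at least 2-fold, and 18 lists. Among lists the block added the matrix-degrading proteases (adjusted p 0.0427), and it changed no other call of a list. Among the 137 named genes it added 5 calls, Plin2, Lyz2, Ramp2, Erg and Emcn, and ended 0. Of 123 named genes called, 102 kept their call in every setting that tested them. Of the 17 lists, 11 kept theirs in every setting with the preset correlation: collagens, Wnt targets, cholesterol synthesis, unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, immediate early genes, complement, FAP identity, NRF2 targets and myogenic cells. The myogenic list was not called by fry (adjusted p 0.0934). The myofibre list lost its call most often, and 5 lists not called in the main test were called in some setting. Depth limits the low genes most: control replicate 3 detected 15255 genes, and 1 read there is worth 4.25 units of the normalised count.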

Other observations

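Families of genes sharing a symbol root were tested after the data had been seen, 104 families with at least 12 members of a mean of 20 or more. Of 48 mitochondrial ribosomal protein genes of the large subunit (Mrpl), 44 were lower and 0 higher (median log2 fold change -0.68, camera adjusted p 3.33e-17, and adjusted p = 0.493 with an estimated correlation), and of 29 of the small subunit (Mrps), 25 were lower and 0 higher (adjusted p 9.75e-10, and adjusted p = 0.493 with an estimated correlation). Genes with the symbol root Rpl were lower at 49 of 58 and higher at 0, and those with the root Rps lower at 39 of 51 and higher at 1. These roots take in cytosolic ribosomal protein genes and also other genes, as only 99 ribosomal protein genes were counted among all genes. Proteasome regulatory subunit genes (Psmd) were lower at 14 of 14. Genes with the root Eif, which takes in the translation initiation factors, were lower at 32 of 54 and higher at 5. None of these families was called with an estimated correlation (adjusted p 0.493 or 0.497). The medians of Mrpl, Rpl, Rps, Mrps, Psmd and Eif were -0.68, -0.72, -0.71, -0.56, -0.53 and -0.42, and -0.39, -0.22, -0.21, -0.38, -0.43 and -0.36 with the length trend removed. Ribosomal protein genes have processed copies in the genome, so their reads are uncertain. Among clustered protocadherin genes, which encode adhesion proteins, 9 of 12 of the Pcdhga cluster were higher and 0 lower (median 0.76, camera adjusted p 3.24e-04, and adjusted p = 0.497 with an estimated correlation, and 0.00219 with the length trend removed, where the median was 0.55), and 6 of 18 of Pcdhb were higher and 0 lower (median 0.62, camera adjusted p 0.00944, and adjusted p = 0.551 with an estimated correlation, and 0.0605 with the length trend removed). Genes of the Pcdhga cluster share exons, so their reads are uncertain.

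All 15 genes of the mitochondrial chromosome were lower with C1q, with a median change of 2.54-fold. Over the 13 with a transcript length the median log2 fold change was -1.26, and -0.75 with the length trend removed, where 9 of the 13 were called lower. The most abundant, COX1, went from 429895 ± 52826 to 192787 ± 23832 (log2 fold change -1.16, adjusted p 0.00749), and the ribosomal RNA gene mt-Rnr2 from 66729 ± 13431 to 18708 ± 3061 (-1.83, adjusted p 3.97e-04). Control replicate 3 differed from the rest in another way: COX2 stood at 1.84% of COX1 there and at 0.929% to 1.10% in the other 5 libraries, and COX3 at 1.57% against 0.630% to 0.972%. The share of reads on IDs without a symbol was 0.523% and 0.727% in C1q replicates 1 and 3 and 1.88% to 2.01% in the other 4 libraries.

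Of the tests that follow, those of transcript length, RNA integrity, muscle cells and equal depth were chosen after the data were seen, and that of other splits was planned. The pattern was that fold changes followed transcript length (Spearman correlation 0.47 across genes). The slope of a library's deviation on transcript length, in log2 units per doubling, was -0.14, -0.21 and -0.12 in the controls and 0.14, 0.16 and 0.17 with C1q. Length bias alone would leave the called lists near 0 once the trend is removed. With the trend removed and the replicate block, the median over 258 members of the lists called lower was -0.448 (95% bootstrap interval over members -0.541 to -0.415, before -0.619). Over 175 members of the lists called higher it was 0.445 (0.321 to 0.567, before 0.582). The trend fitted on the longest annotated transcript therefore accounted for a share of the shift and not for all of it. Whether length is the whole cause stays undecided, because the lists were called in these same libraries. The interval also treats correlated members as independent. A difference in RNA integrity or library chemistry between the groups could give the trend and cannot be told apart from an effect of C1q on transcripts by length, because the slopes, which differ by 0.313 between the groups, do not overlap.

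Muscle-lineage genes were lower with C1q, with a median log2 fold change of -1.22 over 37 genes, 15 called lower and 2 higher (Myh2 and Myh7), or -0.77 with 14 lower without control replicate 1. With the trend removed and the block the median was -1.11 (-1.50 to -0.91), so the fitted length trend accounted for little of this fall. A candidate explanation is that the sorted cells held a different share of myogenic cells in each library, although the sort should remove them. Genes of the myogenic list were clearly expressed: Myog stood at 2356, 1269 and 718 in controls 1 to 3 and 438, 528 and 498 with C1q. Myod1 stood at 1386, 686 and 451, then 236, 271 and 268. Pax7 and Myf5 were low (at most 7.58 and 17.0). How many of the 37 genes FAPs express themselves is not known from these libraries. Of the 27 genes with a control mean of at least 100, 92.6% shared the order of replicate 1 above 2 above 3 over the controls, against a median of 29.6% and a highest of 59.3% in 10000 random lists of the same size and expression, but genes regulated together within cells would share an order too, so this does not separate a different share of cells from regulation. Within same-numbered pairs 35, 34 and 21 of the 37 genes were lower with C1q in pairs 1, 2 and 3, and with the replicate block 20 were called lower. Abundant members such as Acta1 (30104, 17937 and 7792 in controls 1 to 3, then 5423, 8581 and 7088 with C1q) and Des, which the pericyte list also holds (14140, 8149 and 4073, then 3054, 4165 and 3843) were lower with C1q in every pair, least in pair 3. Whether C1q lowered these genes within cells or the share of myogenic cells differed cannot be told apart.

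Depth differed between libraries, but with every library thinned to the reads of the shallowest the count of changed genes was 4976 against 6389, within the 1.5-fold bound set before that result was seen, which argues against depth as the cause. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The other splits put control and C1q libraries on both sides, so any difference between the groups adds to their spread and lowers their counts. They therefore cannot tell an effect of C1q from another difference between the groups. The real split gave 6389 changed genes and 1381 at least 2-fold, and was the only 1 of the 10 to reach either count, with a highest of 0 in the other splits, where 104 to 684 genes had an unadjusted p below 0.05 in limma-trend, against 7936, and edgeR called 0. For gene lists called by camera, 3 of the 10 splits gave at least the 17 of the real one, and the highest other split also gave 17. Of the 3 other splits that part all 3 replicate pairs, as the real one does, 1 gave 17 lists and the others 9 and 12, and each gave 0 genes.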
